A study of Homo sapiens with 12 samples.

How the data were processed

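RNA from 12 cultures of VCaP cells, 3 for each of vehicle, 0.1 nM DHT, 10 µM enzalutamide and 10 µM enzalutamide with 100 nM dexamethasone for 24 h, had been hybridized by the authors to Illumina BeadChips as labelled cRNA, with 1 array per culture. The deposited intensity of each probe on each array is the mean over its beads as GenomeStudio gave it (version not stated), not normalized between arrays, and its values (66.1 to 18955) show no subtracted background. The deposited detection p-value of a probe is, from its steps, the share of 770 negative controls at or above it. The deposited numbers of beads per probe are another column of the same table, used here only to describe the arrays. A second deposited table holds intensities processed by the authors, on a linear scale; from the values these were background-subtracted (29.4% to 29.5% below 0) and quantile-normalized (column medians 7.44 to 7.47), and each column had a rank correlation of 1 with the same array's unprocessed intensities. It was used as an alternative, with 42.5 added before the log2.

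Background correction and normalization used neqc of limma 3.58.1 in R 4.3.3 with an offset of 16, quantile normalization and the detection p-values in place of control probes. Probes detected at p under 0.05 on at least 3 of the 12 arrays were kept, 20265 of 47322 (42.8%). In the platform annotation 30112 probes had 1 gene symbol, 8 had several, and 17202 were not listed and are unnamed here. Symbols were checked through their gene identifiers, and 0 changed. Each gene was represented by its kept probe with the highest mean, which gave 11414 genes, 2863 of them with more than 1 kept probe, and the text says where the probes of a named gene had changes of opposite sign. The 5296 kept probes with no single gene were tested apart. Probes of near-identical genes (ORM1 and ORM2, UGT2B15 and UGT2B17, the metallothioneins, KLK2 and KLK3, AKR1C members) were not tested for cross-hybridization.

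A linear model with a mean per group was fitted with lmFit and eBayes (8 residual and 3.71 prior degrees of freedom), with two-sided tests and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. The comparisons were DHT against vehicle, enzalutamide against vehicle, the combination against enzalutamide, the combination against vehicle, and the difference between the dexamethasone change (combination minus enzalutamide) and the DHT change (DHT minus vehicle). The first and the third share no array. Enzalutamide against vehicle shares the vehicle arrays with DHT against vehicle and the enzalutamide arrays with the third comparison, so 100 simulations of unchanged groups were set beside their correlations. With 3 arrays against 3, an exact test of 1 gene cannot go below 0.1. For a gene detected on no array of 1 group by any of its probes, the fold is a bound: the mean of the brighter group against, on each dim array, the higher of the lowest signal among detected probes and the gene's own. Genes whose groups did not overlap numbered 4244 (37.2%), 2299 (20.1%), 2679 (23.5%) and 1990 (17.4%) in the 4 comparisons of groups, where chance gives 10%, and unadjusted p was under 0.05 for 3840, 1660, 1685 and 1340 genes.

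The 22 gene lists, the comparisons, the tests, the rule for named genes and the alternatives, but for the technical division and a minimum of 1.5-fold for DHT calls as a set, were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01), adjusted over the lists within a comparison, with an estimated correlation and with fry beside it. Of the 35 list results of the 4 group comparisons that passed, the 9 for which the text gives a p with an estimated correlation above 0.05 were lost with it and the others held; with genes at their bounds 0 of the 35 medians changed sign. List tests of the difference between dexamethasone and DHT were added later. Some genes belong to more than 1 list, so the list results are not independent. FKBP5, MT2A, MT1X and NFKBIA are glucocorticoid-induced members that also stand in the androgen-induced, metallothionein or NF-kB list. KLK3 is in the androgen-induced and luminal lists, and UGT2B15 and UGT2B17 in the androgen-repressed and androgen synthesis lists. Steroid receptors (1 gene tested) and the basal, stromal and immune lists (4 genes each) had too few tested genes. The rule named the 10 largest rises and falls past the threshold with groups that did not overlap, up to 4 members of each list (2 as values where none passed), a fixed set of receptor target genes in every comparison, and for the overlap and the difference the 10 with the smallest adjusted p in each direction. Entries without an approved symbol (1 among the falls with dexamethasone) were passed over in the largest changes.

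Alternatives were no filter and a stricter filter on dim probes (detection p under 0.01 on all arrays of a group), no background correction, normexp with an offset of 50, scaling of the arrays to a common median, the authors' processed intensities, the replicate number as a block, trend and robust spread, the compared groups alone, array weights, the mean of a gene's probes, a minimum of 1.5-fold, and each array left out in turn. A technical division into 6 and 6 arrays, taken from the sign of the first principal component of the ranks of 19189 probes detected on no array, was added after the data were seen, as a block and as separate fits. It also parts the arrays by mean beads per probe (20.7 to 21.8 and 22.1 to 22.9) and holds 2, 2, 1 and 1 arrays of vehicle, DHT, enzalutamide and combination in the first set. In simulated data with known changes, a log2 change of 0.5 was recovered for 31.9% to 46.4% of changed genes, 1 for 89.7% to 96.9%, and 2 for 95.3% to 98.6%. The simulated noise was independent between genes, and few genes were changed (151 called in the DHT simulation, against 2476 in the data). A call then needs a smaller unadjusted p, so the recovery for DHT does not give the power of the DHT comparison.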

Results

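Gene expression was measured on 12 Illumina BeadChip arrays of VCaP cells, an established human prostate cancer line that grows in response to androgen and carries a fusion of TMPRSS2 with ERG. Cells in complete medium were treated for 24 h with vehicle, with 0.1 nM dihydrotestosterone (DHT, an androgen), with 10 µM enzalutamide (an antiandrogen), or with 10 µM enzalutamide plus 100 nM dexamethasone (a glucocorticoid). Each of the 4 groups held 3 arrays. Mean intensity per array lay between 271 and 344 on 11 arrays and was 199 on vehicle replicate 3, the dimmest. Between 15852 probes (33.5%, vehicle replicate 3) and 18352 probes (vehicle replicate 2) of 47322 were detected per array. Normalized log2 intensities correlated at 0.988 to 0.994 between arrays of a group and at 0.972 to 0.992 between groups. The number of arrays limits the precision.

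Values below are log2 changes ± SE of the linear model with n = 3 arrays per group, and p-values are adjusted over the 11414 genes tested unless said otherwise. For every gene named as changed in a comparison of 2 groups, all 3 arrays of one group lay above all 3 of the other. Where a gene was not detected on any array of the dimmer group, the change is given as a bound ("at least"). The 3 probes of NR3C1, which encodes the glucocorticoid receptor, were detected on 0 arrays, as was the probe of PER1.

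DHT raised androgen-induced genes as a list and lowered androgen-repressed ones. FKBP5, a co-chaperone of steroid receptors, rose by 2.39 ± 0.10 (5.23-fold, adjusted p = 5.82e-08). The largest rise was that of NCAPD3, a condensin subunit (3.11 ± 0.12, adjusted p = 5.82e-08), and the largest fall that of REG4, a secreted lectin (-3.31 ± 0.10, adjusted p = 1.04e-08). The comparison with vehicle measured what additional androgen did in medium that already held serum. Of the 11414 genes, 2476 changed, 1259 up and 1217 down, and 890 changed by at least 1.5-fold.

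Among the 10 largest rises were also SERPINA3, a protease inhibitor detected on 1 of the 3 vehicle arrays (2.49 ± 0.15), ORM2, an acute-phase protein detected on 2 vehicle arrays (2.32 ± 0.14), EMP1 (2.29 ± 0.23), the sialyltransferase ST6GAL1 (2.10 ± 0.14) and the glucose transporter SLC2A3 (2.09 ± 0.12). RDH10, a retinol dehydrogenase (1.99 ± 0.11), EAF2, a partner of the elongation factor ELL (1.97 ± 0.11), and NBL1 (1.96 ± 0.09) completed them. The falls after REG4 were CCN3 (-2.29 ± 0.12), the chemokine receptor ACKR3 (-2.18 ± 0.13), MIR99AHG (-2.15 ± 0.12), ASZ1 (-2.04 ± 0.14), the phospholipase PLA2G2A (-2.03 ± 0.12), the kappa opioid receptor OPRK1 (-1.98 ± 0.11), SLC3A1 (-1.95 ± 0.13), the fatty acid binding protein FABP5 (-1.88 ± 0.12) and CAMKV (-1.79 ± 0.11). CCN3 was detected on 2 and ASZ1 on 1 of the 3 DHT arrays.

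Of 32 androgen-induced genes tested, 27 rose and 1 fell, and adjusted over the list alone 29 rose and 1 fell (median 0.76, camera adjusted p = 1.42e-20). TMPRSS2, a membrane serine protease, rose by 1.49 ± 0.08, LRIG1 by 1.37 ± 0.09, STEAP4 by 1.29 ± 0.16 (detected on 1 of 3 vehicle arrays), KLK3, which encodes prostate-specific antigen, by 1.02 ± 0.12, SLC45A3 by 0.93 ± 0.08, ERG by 0.88 ± 0.10 and KLK2 by 0.58 ± 0.08. The member that fell was the prostaglandin receptor gene PTGER4 (-0.41), named after its value was seen. Of 8 androgen-repressed genes, 6 fell (7 adjusted over the list alone; median -0.84, adjusted p = 5.07e-07), among them FOLH1, which encodes prostate-specific membrane antigen (-1.52 ± 0.15), and CAMK2N1 (-0.94 ± 0.13).

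Lists of lipid synthesis, endoplasmic reticulum (ER) stress and polyamine genes shifted up with DHT. Of 18 sterol synthesis genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.36, adjusted p = 0.000187), led by INSIG1 (0.77 ± 0.09), a sterol-regulated gene, with IDI1 (0.74 ± 0.10) and NSDHL (0.64 ± 0.09), while TM7SF2 fell (-0.67 ± 0.09). Of 13 fatty acid synthesis genes, 6 rose (6 adjusted over the list alone; median 0.26, adjusted p = 0.00387), with ELOVL7 (0.87 ± 0.24), FASN, the fatty acid synthase (0.75 ± 0.08), ELOVL5 (0.70 ± 0.15) and ACLY (0.57 ± 0.10). Of 14 ER stress genes, 10 rose (11 adjusted over the list alone; median 0.56, adjusted p = 1.04e-06), with DNAJC3 (0.99 ± 0.20, detected on 1 vehicle array), EDEM1 (0.98 ± 0.10), HYOU1 (0.73 ± 0.13) and PDIA4 (0.63 ± 0.11). Of 10 polyamine genes, 5 rose (6 up and 1 down adjusted over the list alone; median 0.40, adjusted p = 0.0067): the spermine synthase SMS (1.03 ± 0.08), the ornithine decarboxylase ODC1 (0.98 ± 0.09), SAT1 (0.63 ± 0.10), SMOX (0.55 ± 0.15) and, named after its value was seen, AMD1 (0.36 ± 0.11).

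Of 10 prostate luminal genes, 6 rose (7 adjusted over the list alone; median 0.35, adjusted p = 0.000102), including AMACR (1.22 ± 0.10), KRT19 (1.08 ± 0.10) and KRT18 (0.47 ± 0.14, with probes of opposite sign). Of 26 glucocorticoid-induced genes, 9 rose and 3 fell (11 and 4 adjusted over the list alone; median 0.18, adjusted p = 0.0156). The members that rose include ERRFI1 (1.77 ± 0.09), the kinase SGK1 (1.32 ± 0.17) and the transcription factor ZBTB16 (0.58 ± 0.09), and TMT1A fell (-0.81 ± 0.10), while KLF9 (0.30 ± 0.11) and TSC22D3 (0.32 ± 0.15) did not pass. Of 8 genes of androgen synthesis and inactivation, 3 fell (3 adjusted over the list alone; median -0.21, adjusted p = 0.038, and adjusted p = 0.0828 with an estimated correlation): AKR1C3 (-0.94 ± 0.09), UGT2B17 (-0.73 ± 0.11) and HSD17B6 (-0.66 ± 0.09).

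Of 29 cell cycle genes, 3 rose and 9 fell (9 and 9 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.515), with a median of 0.12, a mean of -0.14 and a test pointing down. The genes that fell encode the replication helicase and related enzymes, among them MCM2 (-1.48 ± 0.09), MCM4 (-1.35 ± 0.09), MCM5 (-1.08 ± 0.12) and MCM6 (-1.03 ± 0.08). The mitotic genes CCNA2 (0.36 ± 0.12), KIF20A (0.34 ± 0.10) and CDK1 (0.28 ± 0.09), named after their values were seen, rose, but none of the 3 calls held without vehicle replicate 3, and under median scaling CCNA2 alone passed.

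The remaining lists did not pass with DHT. Of 14 hypoxia and glycolysis genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), with ANKRD37 (1.65 ± 0.16, detected on 2 vehicle arrays), NDRG1 (0.80 ± 0.12), EGLN3 (-0.61 ± 0.17) and ADM (-0.45 ± 0.09). Of 7 neuroendocrine genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone): SCG2 (0.75 ± 0.10), INSM1 (0.42 ± 0.11, named after its value was seen), DLL3 (-0.57 ± 0.08), CHGB (-0.44 ± 0.12) and ENO2, at least 1.52-fold lower. The NF-kB genes NFKBIA (0.64 ± 0.08) and CXCL8 (0.64 ± 0.17), the metallothionein MT1F (0.82 ± 0.15), the chaperones HSPA1A (0.61 ± 0.12), BAG3 (0.46 ± 0.09) and HSP90AB1 (-0.28 ± 0.08) and the reference genes PPIA (-0.77 ± 0.14), B2M (0.62 ± 0.11) and HPRT1 (-0.60 ± 0.09) changed as single members. No interferon or circadian gene passed; the largest changes were 0.26 ± 0.10 (IRF9), -0.24 ± 0.22 (IFI35), -0.50 ± 0.20 (NR1D2) and -0.49 ± 0.23 (DBP).

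**Figure D1:**
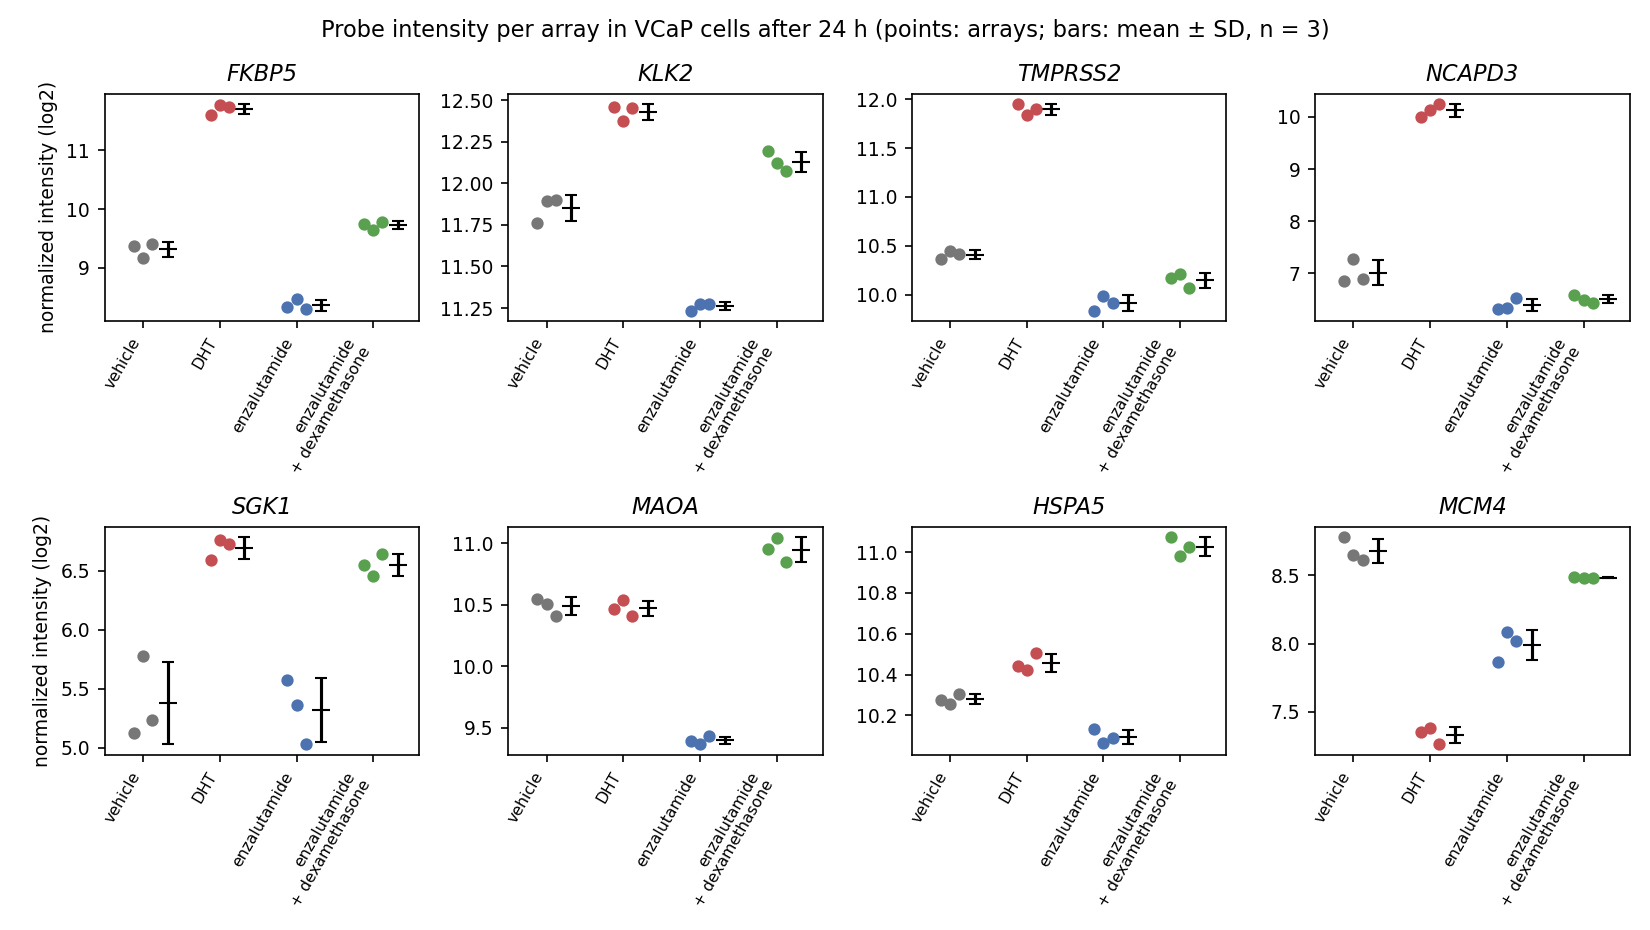
Normalized log2 intensity (vertical axis) of 8 genes on each array (points) of the 4 groups (horizontal axis), with mean ± SD of 3 arrays (bars). FKBP5, KLK2, TMPRSS2 and NCAPD3 lay highest with DHT, MAOA and HSPA5 highest with enzalutamide plus dexamethasone, and MCM4 lowest with DHT.

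A technical division of the arrays was found in the probes that no array detected: 6 arrays (vehicle and DHT replicates 1 and 2, enzalutamide and combination replicate 1) differed in sign from the other 6 on the first principal component. That component held 12.5% of the variance and mostly set vehicle replicate 3 apart. This array lay at 519056, the others of its set at 37899 to 73957 and the first set at -213417 to -92898. The division was found after the data were seen, and results are given with it as a block and within each set. Here and in the comparisons below, signs within a set are given for genes called in the fit of all 12 arrays. That fit includes the arrays of the set, so kept signs follow in part from the selection and are no independent replication. For DHT against vehicle, 2661 genes changed with the block, 995 within the first set and 329 within the second, each with fewer arrays, and 2425 of 2426 and 2399 of 2403 called genes tested again kept their sign there. Scaling arrays to a common median in place of quantile normalization moved the median of all genes by 0.16 and gave 1169 genes, 950 up and 219 down. Of the 79 called genes that the naming rule chose, 9 then lost their call: ADM, CHGB, DLL3, EGLN3, HPRT1, HSD17B6, HSP90AB1, TM7SF2 and UGT2B17. Leaving out 1 array cost 7 of the 79 their call at least once: CHGB, CXCL8, EGLN3, ELOVL7, HSP90AB1, KRT18 and SMOX. Of the genes named after their values were seen, PTGER4, CDK1 and KIF20A lost their call under median scaling, and AMD1, INSM1, CCNA2, CDK1 and KIF20A without at least 1 array. Cell cycle genes that fell numbered 4 under median scaling and 7 to 9 with 1 array left out. Those that rose numbered 0 to 2 with 1 array left out and 0 without vehicle replicate 3. Hypoxia and glycolysis genes numbered 2 up and 0 down under median scaling. With 1 array left out they numbered 3 to 5 up, moving by over 1.5 times without DHT replicate 2 or 3 or vehicle replicate 2, and 1 to 3 down, moving so without vehicle replicate 2 or DHT replicate 3. Polyamine genes that rose numbered 3 to 6, with 3 without DHT replicate 1 or vehicle replicate 2. Neuroendocrine genes that rose numbered 1 to 2 and NF-kB genes 1 to 2. Genes of androgen synthesis and inactivation that fell numbered 1 under median scaling.

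Enzalutamide lowered androgen-induced genes and raised androgen-repressed ones, against the same vehicle arrays that DHT was compared with. The prostate-restricted calcium channel gene TRPM8 fell by 1.03 ± 0.10 (adjusted p = 0.000304), FKBP5 by 0.96 ± 0.10 (adjusted p = 0.000408) and EAF2 by 1.10 ± 0.11 (adjusted p = 0.000408). CCN3, which DHT lowered, had the largest rise (1.89 ± 0.12, adjusted p = 2.35e-05). In all, 209 genes changed, 95 up and 114 down, and 104 changed by at least 1.5-fold.

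Of 32 androgen-induced genes, 13 fell (19 adjusted over the list alone; median -0.34, camera adjusted p = 1.28e-18). They include ZBTB10 (-0.86 ± 0.18), ERG (-0.75 ± 0.10), SLC45A3 (-0.74 ± 0.08), KLK2 (-0.59 ± 0.08) and TMPRSS2 (-0.49 ± 0.08), and KLK3 was at least 1.22-fold lower (adjusted p = 0.028). STEAP4 was detected on no enzalutamide array and did not pass. Of 8 androgen-repressed genes, 5 rose (6 adjusted over the list alone; median 0.65, adjusted p = 9.67e-11): CCN3, UGT2B17 (0.85 ± 0.11), OPRK1 (0.76 ± 0.11), BCHE (0.68 ± 0.12) and UGT2B15 (at least 1.12-fold). Of the 10 largest rises, PTGER2 (1.24 ± 0.13, detected on 1 vehicle array), the matrix protein gene LUM (1.24 ± 0.17), BAMBI (1.13 ± 0.11), LRRC31 (1.02 ± 0.12), MATN2 (0.96 ± 0.10), the DOPA decarboxylase DDC (0.91 ± 0.13), NAALAD2 (0.89 ± 0.14), CCNG2 (0.88 ± 0.11) and ERP27 (0.85 ± 0.10) followed CCN3. The largest falls were SLC2A3 (at least 2.31-fold, adjusted p = 3.86e-05), GDF11 (-1.26 ± 0.09, with probes of opposite sign), EAF2, the glutamate receptor subunit GRIN3A (-1.10 ± 0.12), ENDOD1 (-1.09 ± 0.10), MYBPC1 (-1.09 ± 0.14), the monoamine oxidase MAOA (-1.09 ± 0.08), CFAP69 (-1.07 ± 0.09), TRPM8 and ZBTB16 (-1.01 ± 0.09).

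Of 18 sterol synthesis genes, 5 fell (9 adjusted over the list alone; median -0.30, adjusted p = 1.2e-07): HMGCS1 (-0.68 ± 0.08), INSIG1 (-0.65 ± 0.09), EBP (-0.54 ± 0.10), MSMO1 (-0.43 ± 0.09, with probes of opposite sign) and DHCR7 (-0.34 ± 0.08). Of 13 fatty acid synthesis genes, FADS1 fell (-0.43 ± 0.09; 2 fell adjusted over the list alone), and the list passed (median -0.11, adjusted p = 0.00882) but its median was 0.03 under median scaling, where all genes moved by 0.13. Of 29 cell cycle genes, MCM4 (-0.69 ± 0.09), MCM5 (-0.59 ± 0.12) and MCM2 (-0.48 ± 0.09) fell (1 up and 10 down adjusted over the list alone; median -0.08, adjusted p = 0.000613, median 0.08 under median scaling). Of 14 ER stress genes, SDF2L1 fell (-0.48 ± 0.09; 2 adjusted over the list alone; median -0.16, adjusted p = 0.00363, and adjusted p = 0.0653 with an estimated correlation). Of 26 glucocorticoid-induced genes, 5 fell and 1 rose (5 and 4 adjusted over the list alone; median -0.06, adjusted p = 0.0438, and adjusted p = 0.0733 with an estimated correlation; median 0.07 under median scaling): MAOA, ZBTB16, ANGPTL4 (1.99-fold lower, with probes of opposite sign), FKBP5, CEBPD (-0.65 ± 0.11) and, upward, RGS2 (0.57 ± 0.11). CEBPD, RGS2 and DHCR7 were named after their values were seen, and their calls were lost under median scaling and without at least 1 array.

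Genes of androgen synthesis and inactivation went both ways and the list of 8 did not pass (adjusted p = 0.101; 4 up and 1 down adjusted over the list alone): UGT2B17, UGT2B15 and AKR1C3 (0.50 ± 0.09) rose and HSD17B6 fell (-0.73 ± 0.09). NR3C2, the mineralocorticoid receptor, fell by 0.56 ± 0.12. Of 10 luminal genes KLK3 alone passed (3 down adjusted over the list alone), and no metallothionein, neuroendocrine, interferon, NF-kB, circadian, polyamine, heat shock, hypoxia or housekeeping gene did. The largest changes in these lists were 0.51 ± 0.24 (IFIT2), 0.48 ± 0.20 (NR1D2), 0.41 ± 0.14 (CHGA), 0.40 ± 0.16 (ANKRD37), -0.39 ± 0.11 (INSM1), -0.29 ± 0.15 (SMOX), -0.24 ± 0.09 (STIP1) and -0.16 ± 0.09 (HPRT1). SGK1 (-0.06 ± 0.17, with probes of opposite sign), TSC22D3 (0.49 ± 0.15) and KLF9 (-0.11 ± 0.11) did not pass.

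Leaving out vehicle replicate 1, 2 or 3 gave 106, 132 or 133 genes for enzalutamide against vehicle, and leaving out enzalutamide replicate 1, 2 or 3 gave 76, 93 or 79. Median scaling gave 48 genes (34 up and 14 down). The androgen-induced genes that fell numbered 8 to 10 with 1 array left out and 3 under median scaling. They numbered 8 without vehicle replicate 1 or any enzalutamide replicate. The androgen-repressed genes that rose numbered 3 to 5 with 1 array left out (3 without replicate 1 or 3 of either group) and 3 under median scaling. Sterol synthesis genes that fell numbered 2 to 3 without any 1 of the 6 arrays, and cell cycle genes 1 to 2 (1 without vehicle replicate 3 or any enzalutamide replicate), with 0 of either under median scaling. Genes of androgen synthesis and inactivation that rose numbered 1 to 3 with 1 array left out, moving by over 1.5 times without vehicle replicate 1 or enzalutamide replicate 1 or 3, and 1 under median scaling, where 0 fell. AKR1C3 and UGT2B15 each lost their call without 4 of the 6 arrays. The call of SDF2L1 was lost under median scaling and without any array but vehicle replicate 2. With the technical division as a block 246 genes changed. Within each set alone limma called 0 genes (997 and 1569 at an unadjusted p under 0.05), with 1 enzalutamide array in the first set and 1 vehicle array in the second, assumed to vary like the other groups, while 200 of 200 and 200 of 201 called genes tested again kept their sign. Of the 44 called genes that the rule chose, 20 lost their call under median scaling, among them KLK2, KLK3, TMPRSS2, SLC45A3, ERG, MCM2, MCM4 and MCM5, with no change of sign. The calls of NR3C2 and FADS1 were lost without any 1 of the 6 arrays, and those of 11 others, including KLK3, MCM2, MCM5, ZBTB10 and BCHE, without some of them.

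Adding dexamethasone to enzalutamide raised glucocorticoid-induced genes, part of the androgen-induced genes and ER stress genes, and lowered androgen-repressed genes. The comparison with enzalutamide alone asked what the glucocorticoid did while enzalutamide was present. The lipase inhibitor ANGPTL4 rose most (1.89 ± 0.13, adjusted p = 2.13e-05), the androgen and glucocorticoid target FKBP5 rose by 1.36 ± 0.10 (adjusted p = 2.13e-05), and the ER chaperone HSPA5 rose by 0.93 ± 0.07 (adjusted p = 5.17e-05). The largest fall was that of DDC (-1.39 ± 0.13, adjusted p = 0.000128). In all, 400 genes changed, 204 up and 196 down, and 160 changed by at least 1.5-fold.

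After ANGPTL4 the largest rises were MYBPC1 (1.70 ± 0.14), ZBTB16 (1.56 ± 0.09), MAOA (1.55 ± 0.08), the epithelial sodium channel subunit SCNN1A (1.49 ± 0.09), SPSB1 (at least 2.29-fold), FKBP5, GRIN3A (1.31 ± 0.12), RGS4 (1.25 ± 0.10) and PGLYRP2 (at least 1.90-fold, detected on no array of the other groups). After DDC the largest falls were OPRK1 (-1.34 ± 0.11), ACKR3 (-1.32 ± 0.13), SCUBE2 (-1.18 ± 0.11), CCN3 (-1.17 ± 0.12), CAPN5 (-1.10 ± 0.10), MIR99AHG (-1.09 ± 0.12, with probes of opposite sign), CNTNAP2 (-1.09 ± 0.10), PEG10 (-1.08 ± 0.12) and PLAAT4 (-1.07 ± 0.10).

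Of 26 glucocorticoid-induced genes, 10 rose (14 up and 1 down adjusted over the list alone; median 0.49, camera adjusted p = 3.03e-15), among them SGK1 (1.23 ± 0.17) and the transcription factor KLF9 (2-fold, adjusted p = 0.000362), while TSC22D3 (-0.14 ± 0.15) did not pass. Of 32 androgen-induced genes, 12 rose (15 adjusted over the list alone; median 0.29, adjusted p = 1.8e-14), including EAF2 (1.25 ± 0.11), PLPP1 (0.93 ± 0.09), ELL2 (0.92 ± 0.09), KLK2 (0.87 ± 0.08), SLC45A3 (0.73 ± 0.08), KLK3 (at least 1.30-fold) and ERG (0.46 ± 0.10). TMPRSS2 (0.23 ± 0.08) did not pass, and STEAP4 was detected on no array of either group. Of 8 androgen-repressed genes, 4 fell (6 adjusted over the list alone; median -0.63, adjusted p = 9.78e-10): OPRK1, CCN3, UGT2B17 (-0.81 ± 0.11) and CAMK2N1 (-0.67 ± 0.13).

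Of 14 ER stress genes, 7 rose (10 adjusted over the list alone; median 0.69, adjusted p = 1.27e-15), and all 14 had positive changes. SDF2L1 (1.02 ± 0.09), the disulfide isomerase PDIA4 (0.97 ± 0.11), HSPA5 and CRELD2 (0.90 ± 0.09) changed most. Of 18 sterol synthesis genes, INSIG1 (0.55 ± 0.09), HMGCS1 (0.35 ± 0.08) and SQLE (0.34 ± 0.08) rose (7 adjusted over the list alone; median 0.20, adjusted p = 0.000227). Of 13 fatty acid synthesis genes 0 passed (0 adjusted over the list alone), with 0.30 ± 0.15 for ELOVL5 and 0.28 ± 0.10 for ACLY, and the list passed (median 0.19, adjusted p = 0.0355, and adjusted p = 0.0703 with an estimated correlation). Of 29 cell cycle genes, MCM4 rose (0.49 ± 0.09; 1 adjusted over the list alone; median 0.11, adjusted p = 0.00202). Of 5 metallothioneins, MT1G rose (at least 1.27-fold; 4 adjusted over the list alone; median 0.53, adjusted p = 0.000623, median 0.37 with MT1G at its bound). Of 8 NF-kB genes, the chemokine genes CCL2 (0.85 ± 0.14) and CXCL8 (0.71 ± 0.17, with probes of opposite sign) rose (3 adjusted over the list alone; median 0.20, adjusted p = 0.00309). PFKFB3, a regulator of glycolysis, rose by 0.44 ± 0.09 among 14 hypoxia and glycolysis genes (1 adjusted over the list alone; median 0.16, adjusted p = 0.0148).

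Of 11 interferon genes 0 passed (0 adjusted over the list alone), 10 had negative changes, and the list passed downward (median -0.15, adjusted p = 0.0386, and adjusted p = 0.0736 with an estimated correlation), with -0.39 ± 0.16 for MX1 and -0.38 ± 0.24 for IFIT2. The luminal list passed upward (median 0.10, adjusted p = 0.0485, and adjusted p = 0.179 with an estimated correlation; 2 up and 1 down adjusted over the list alone), with KLK3 as the member that rose. Among 8 genes of androgen synthesis and inactivation, HSD17B6, an enzyme of androgen metabolism, rose (1.13 ± 0.09) and UGT2B17 and AKR1C3 (-0.60 ± 0.09) fell, and the list did not pass (adjusted p = 0.579). NR3C2 rose by 0.70 ± 0.12 and ENO2 fell by 0.49 ± 0.11. No circadian, polyamine, heat shock or housekeeping gene passed, and neither these lists nor the neuroendocrine list did. Among the largest changes there were -0.66 ± 0.20 (NR1D2), -0.48 ± 0.23 (DBP), 0.40 ± 0.15 (SMOX), -0.29 ± 0.16 (HSPB1) and 0.27 ± 0.09 (HPRT1). The circadian list had a positive median (0.02) and a negative mean (-0.10).

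**Figure D2:**
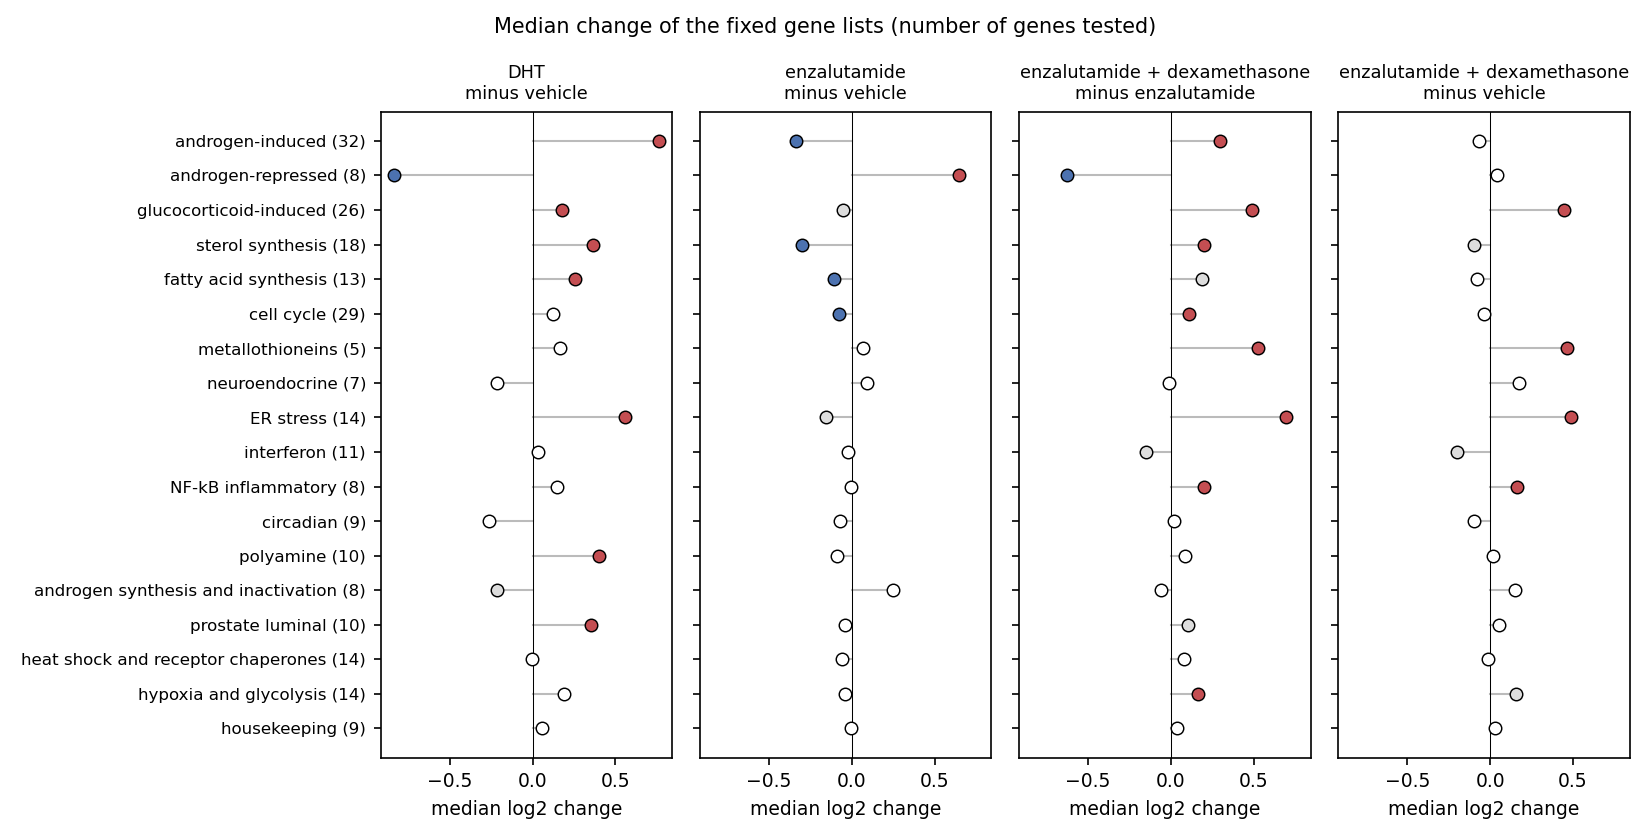
Median log2 change (horizontal axis) of each list with at least 5 tested genes (vertical axis, number tested in parentheses) in the 4 comparisons of groups. Red (up) and blue (down) points passed camera with the preset and with the estimated correlation, grey points with the preset one only, and open points passed neither; the medians of the glucocorticoid-induced, fatty acid synthesis and cell cycle lists with enzalutamide and of the sterol synthesis list in the combination against vehicle turned positive under median scaling, but stayed below the median of all genes there.

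Leaving out enzalutamide replicate 1, 2 or 3 gave 219, 228 or 227 genes for dexamethasone, and leaving out combination replicate 1, 2 or 3 gave 245, 224 or 230. Median scaling, which moved the median of all genes by 0.07, gave 108 genes (73 up and 35 down). The ER stress genes that rose numbered 7 without any 1 of the 6 arrays and under median scaling, the androgen-induced genes 8 to 10 and 6, and the sterol synthesis genes 1 to 2 and 0. With the technical division as a block 439 genes changed. Within the first set, with 1 array per group, limma called 0 genes (928 at an unadjusted p under 0.05) and within the second 31, while 390 of 391 and 389 of 390 called genes tested again kept their sign. Of the 49 called genes that the rule chose, 12 lost their call under median scaling, among them KLK3, ERG, INSIG1, HMGCS1, SQLE, MCM4 and MT1G. The calls of ENO2 and SQLE were lost without any 1 of the 6 arrays, and those of CAMK2N1, CXCL8, ERG, HMGCS1, LUM, MT1G and PFKFB3 without some of them.

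Against vehicle, cells given enzalutamide plus dexamethasone had higher glucocorticoid-induced, ER stress and metallothionein genes, while androgen-induced genes as a list showed no detected shift. The metallothionein list shares MT2A and MT1X with the glucocorticoid-induced list. SCNN1A rose most (1.38 ± 0.09, adjusted p = 5.38e-05), and SGK1 (1.17 ± 0.17, adjusted p = 0.00849) and HSPA5 (0.75 ± 0.07, adjusted p = 0.000554) rose as well. TRPM8 fell by 1.24 ± 0.10 (adjusted p = 0.000146). In all, 125 genes changed, 76 up and 49 down, and 60 changed by at least 1.5-fold.

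The other large rises were PGLYRP2 (at least 1.84-fold), SPSB1 (1.03 ± 0.17, detected on 2 vehicle arrays), CYP4F22 (at least 1.20-fold), ANGPTL4 (0.90 ± 0.13), KLF9 (0.89 ± 0.11), RGS4 (0.89 ± 0.10), SHISA2 (0.85 ± 0.15) and CCL2 (0.83 ± 0.14). The largest fall was that of SLC2A3 (-1.33 ± 0.12, detected on 1 combination array), followed by ENDOD1 (-1.29 ± 0.10), TRPM8, PKP1 (-1.16 ± 0.10), HES6 (-0.79 ± 0.12), METRN (-0.76 ± 0.12), GDF11 (-0.76 ± 0.09, with probes of opposite sign), TMEM79 (-0.76 ± 0.08), BASP1 (-0.74 ± 0.11) and MMP7 (-0.73 ± 0.15). Of 26 glucocorticoid-induced genes, 9 rose (15 adjusted over the list alone; median 0.44, camera adjusted p = 1.05e-16), including ZBTB16 (0.54 ± 0.09). Of 14 ER stress genes, 6 rose (10 adjusted over the list alone; median 0.49, adjusted p = 7e-14), including PDIA4 (0.65 ± 0.11), DDIT3 (0.63 ± 0.13) and DNAJB9 (0.57 ± 0.10). Of 5 metallothioneins, MT2A rose (0.71 ± 0.14; 4 adjusted over the list alone; median 0.46, adjusted p = 0.000207). Of 8 NF-kB genes, CCL2 and CXCL8 (0.79 ± 0.17) rose (3 adjusted over the list alone; median 0.16, adjusted p = 0.00452).

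Of 32 androgen-induced genes, PLPP1 (0.81 ± 0.09), ELL2 (0.48 ± 0.09) and PTGER4 (0.46 ± 0.10) rose and TRPM8 fell (5 and 2 adjusted over the list alone; median -0.07, adjusted p = 0.788, median 0.15 under median scaling). FKBP5 (0.41 ± 0.10), KLK2 (0.28 ± 0.08), KLK3 (0.08 ± 0.12), SLC45A3 (-0.01 ± 0.08), TMPRSS2 (-0.26 ± 0.08), ERG (-0.29 ± 0.10) and TSC22D3 (0.35 ± 0.15) did not pass. Of 8 androgen-repressed genes, CCN3 rose (0.71 ± 0.12) and OPRK1 fell (-0.58 ± 0.11), with 2 up and 2 down adjusted over the list alone (adjusted p = 0.65). The sterol synthesis list passed downward with 0 single genes past the threshold (2 down adjusted over the list alone; median -0.10, adjusted p = 0.0397, and adjusted p = 0.146 with an estimated correlation), with SREBF2 (detected on no combination array) at least 1.48-fold lower, but its median was 0.15 under median scaling, where all genes moved by 0.21. The interferon list passed downward with 0 single genes (1 adjusted over the list alone; median -0.20, adjusted p = 0.0154, and adjusted p = 0.0532 with an estimated correlation), with -0.51 ± 0.12 for ISG15. The hypoxia and glycolysis list passed upward with 0 single genes (0 adjusted over the list alone; median 0.15, adjusted p = 0.0154, and adjusted p = 0.0532 with an estimated correlation), with 0.57 ± 0.17 for EGLN3. The other lists did not pass and no member did. Among their largest changes were 0.71 ± 0.23 (HSD11B2), -0.49 ± 0.12 (MCM5), -0.50 ± 0.11 (ENO2), -0.35 ± 0.24 (ELOVL7), -0.26 ± 0.10 (BHLHE40), -0.25 ± 0.16 (HSPB1), -0.20 ± 0.08 (HOXB13), -0.19 ± 0.09 (SDHA) and 0.18 ± 0.09 (ODC1). The neuroendocrine list had a positive median (0.17) and a test pointing down.

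Leaving out vehicle replicate 1, 2 or 3 gave 45, 66 or 58 genes for the combination against vehicle, and leaving out combination replicate 1, 2 or 3 gave 47, 32 or 37. Median scaling gave 84 genes, 80 up and 4 down, so that the balance of rises and falls depended on the scaling. The ER stress genes that rose numbered 1 to 4 with 1 array left out (3 or fewer without any but vehicle replicate 1), and the glucocorticoid-induced genes 5 to 9 (5 without combination replicate 2, 6 without vehicle replicate 3). The androgen-induced genes that rose numbered 1 to 2, the metallothioneins 0 to 2 (0 without vehicle replicate 3) and the NF-kB genes 0 to 1. With the technical division as a block 134 genes changed, and within each set alone limma called 0 genes (769 and 1421 at an unadjusted p under 0.05), while 123 of 123 and 121 of 121 called genes tested again kept their sign. Of the 32 called genes that the rule chose, 17 lost their call without at least 1 array, and CXCL8, DDIT3, OPRK1 and PTGER4 lost it without any 1 of the 6. Under median scaling 9 of the 32 lost their call: BASP1, ELL2, GDF11, HES6, METRN, MMP7, OPRK1, PTGER4 and TMEM79.

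The genes that dexamethasone moved in the presence of enzalutamide overlapped with those that DHT moved, on arrays that the 2 comparisons do not share. Among 204 genes raised with dexamethasone, DHT raised 119, against 22.5 if the calls were independent, and among 196 lowered genes DHT lowered 121, against 20.9. Opposite calls were made for 18 and 8 genes, against 21.8 and 21.6. Besides FKBP5, EAF2, MYBPC1, RGS4, ELL2 and SLC45A3, the shared rises with the smallest adjusted p were STK39 (0.92 ± 0.09 with DHT and 0.89 ± 0.09 with dexamethasone), GDF15 (1.25 ± 0.09 and 0.82 ± 0.09), CHPT1 (0.77 ± 0.08 and 0.70 ± 0.08) and MANF (0.70 ± 0.09 and 0.87 ± 0.09). The shared falls were OPRK1, DDC (at least 2.19-fold with DHT), SCUBE2 (-1.69 ± 0.11 with DHT), CCN3, ACKR3, MIR99AHG, PEG10 (-0.93 ± 0.12 with DHT), CAPN5 (-0.75 ± 0.10 with DHT) and SELENBP1 (-1.28 ± 0.11 and -0.90 ± 0.11), and 1 entry without an approved symbol.

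As sets, the 1259 genes raised and the 1217 lowered by DHT moved the same way with dexamethasone. Of the raised genes 73.1% had positive changes (median 0.10; camera p = 7.56e-14, with an estimated correlation p = 7.48e-05), and of the lowered genes 68.7% had negative ones (median -0.10; camera p = 4.78e-11, with an estimated correlation p = 0.000647). For both together the share was 70.9%, and 55.0% of the genes not called with DHT, a difference that was not tested. The rotation test fry of limma, which sets the signed genes against no change and not against other genes, passed at 0.05. Across all 11414 genes, which are not independent replicates, Pearson's r was 0.323 and Spearman's rho 0.265, where 100 simulations of unchanged groups gave r between -0.02 and 0.02. From its width, that range leaves little room for noise shared among genes. In the data, residuals of same-numbered arrays of different groups correlated at up to 0.217. The simulated range therefore does not give the chance of such an r. Under median scaling the share was 80.8%, fry no longer passed at 0.05, and 60 genes were called in both comparisons. Of the 1169 DHT calls there 950 were up, and the median of all genes with dexamethasone was 0.07. The common upward shift can thus raise that share, which is no stronger agreement. The shared calls of 1 direction numbered 240, and 148, 150 and 148 without enzalutamide replicates 1, 2 and 3, and 152 without combination replicate 2 or 3.

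**Figure D3:**
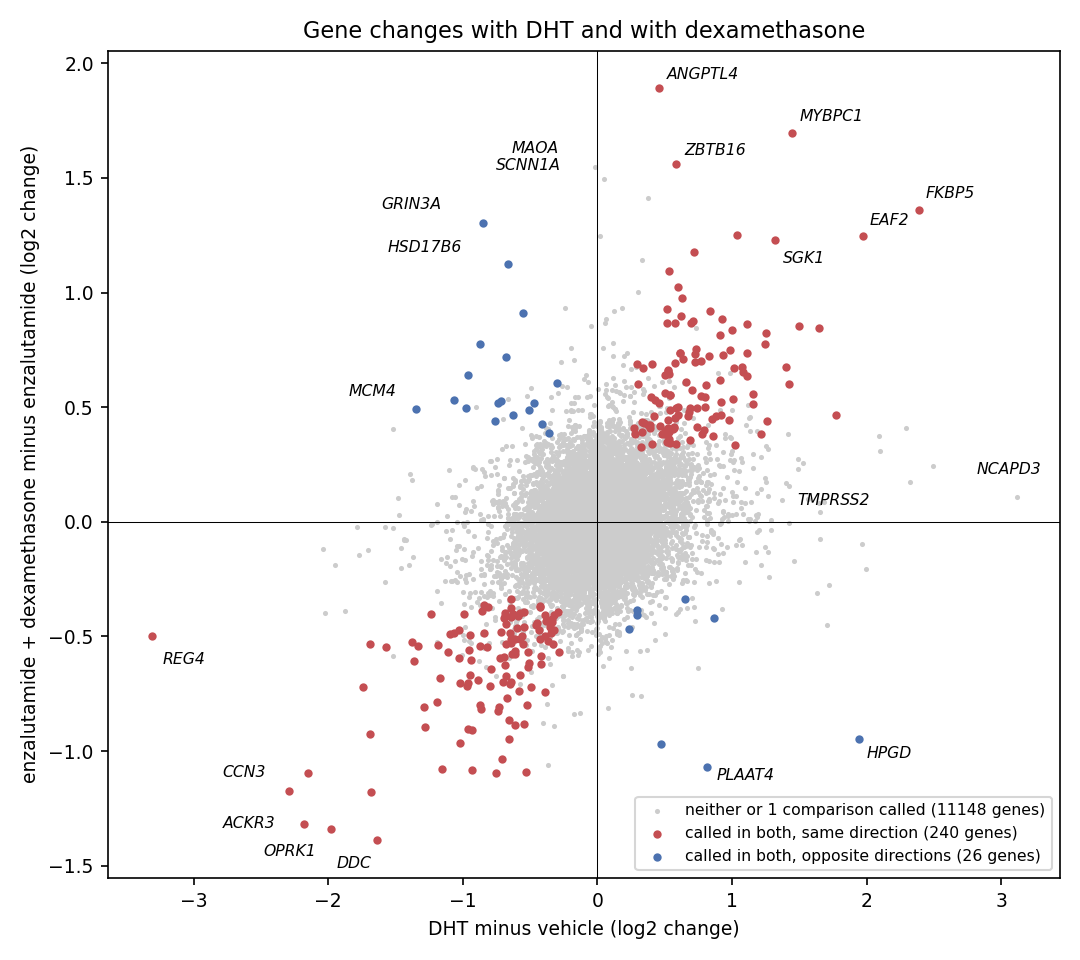
Log2 change with DHT against vehicle (horizontal axis) and with dexamethasone added to enzalutamide (vertical axis) for 11414 genes (points). Of the genes called in both comparisons, 240 changed in the same direction (red) and 26 in opposite directions (blue); FKBP5 and EAF2 rose and CCN3 and ACKR3 fell in both, while HPGD and MCM4 moved apart (DDC with DHT is a fitted value for a gene not detected there).

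The difference between the dexamethasone and DHT changes was called for 788 genes, 412 with the higher and 376 with the lower value for dexamethasone. In 683 of these DHT had been called and had the larger absolute change. HPGD, which inactivates prostaglandins, rose with DHT and fell with dexamethasone (difference -2.89 ± 0.13, adjusted p = 5.79e-07). NCAPD3 (-3.00 ± 0.17), NBL1 (-2.06 ± 0.12), RDH10 (-2.20 ± 0.15), PLAAT4 (-1.88 ± 0.14), IL20RA (-1.94 ± 0.16), TMPRSS2 (-1.25 ± 0.11) and LXN (-1.29 ± 0.13) also had lower values for dexamethasone. MME, detected on no vehicle or combination array, and ORM2, detected on no enzalutamide or combination array, also passed downward and are given no value. REG4, lowered less by dexamethasone, had the smallest adjusted p upward (difference 2.81 ± 0.15, adjusted p = 1.83e-06). It was followed by MCM4 (1.84 ± 0.12), HSD17B6 (1.79 ± 0.13), MAOA (1.57 ± 0.12), WNT2 (1.63 ± 0.12), the replication factor CDC45 (1.40 ± 0.11), CDCA7 (1.56 ± 0.12), GRIN3A (2.16 ± 0.18), TSPAN8 (1.36 ± 0.11) and MCM2 (1.59 ± 0.13). Among these, MCM4, HSD17B6, MAOA, CDC45, GRIN3A and MCM2 had been lowered by enzalutamide, so a return toward vehicle could give part of their differences.

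As lists, androgen-induced genes had lower values for dexamethasone than for DHT (13 of 32 down and 1 up, 18 and 3 adjusted over the list alone; median -0.45, camera adjusted p = 1.9e-08). Glucocorticoid-induced genes had higher ones (8 of 26 up and 2 down, 10 and 3 adjusted over the list alone; median 0.37, adjusted p = 0.0089, and adjusted p = 0.0673 with an estimated correlation). Luminal (median -0.24, adjusted p = 0.00134), polyamine (-0.18, adjusted p = 0.0351) and androgen-repressed genes (0.30, adjusted p = 0.018) passed too, with adjusted p = 0.089, 0.142 and 0.142 with an estimated correlation. The cell cycle list passed upward (adjusted p = 0.0351, and adjusted p = 0.142 with an estimated correlation) with a negative median (-0.10) and a positive mean (0.25). Of 67 genes raised with dexamethasone and not called with DHT, 32 also passed the test of the difference, and of 67 lowered ones 19 did, so for the others a difference from DHT was not shown. Median scaling gave 175 genes for the difference, the technical division as a block 870, and its sets alone 1 and 10 (1309 and 1637 at an unadjusted p under 0.05), with 761 of 761 and 751 of 752 called genes of the same sign.

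Most genes that enzalutamide changed moved back when dexamethasone was present. Of the 209 genes, 115 were called in the opposite direction with dexamethasone, 0 in the same direction, and 199 had a change of opposite sign. Of 114 lowered genes 60 were raised again, among them FKBP5, KLK2, SLC45A3, MAOA, ZBTB16, ANGPTL4 and MYBPC1, and of 95 raised genes 55 were lowered again, among them CCN3, OPRK1, DDC and UGT2B17. The dexamethasone change amounted to 0.796 of the enzalutamide change (median ratio). Both comparisons share the enzalutamide arrays, and 100 simulations without a dexamethasone effect called more genes with enzalutamide (median 968.5). Over the 209 genes of smallest p in each simulation, the ratio was 0.0826 (median of the simulations) and at most 156 had opposite signs. At most 1 called gene was called opposite. As with the correlations, noise shared among genes could widen these simulated values. The simulated enzalutamide changes were also stronger than those in the data, since more genes were called. The 209 genes taken there therefore owe less to noise in the enzalutamide arrays than the 209 called genes. The simulated ratio can thus be too low a measure to set against 0.796, and how much too low was not tested. In the combination, 19 of the 209 genes still differed from vehicle in the direction of enzalutamide, and 13 in the other direction. The number called opposite was 47, 57 and 52 without enzalutamide replicates 1, 2 and 3, 69 and 73 without vehicle replicates 1 and 2, 75 without combination replicate 2, and 27 under median scaling.

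DHT and enzalutamide called opposite directions for 58 genes raised by DHT and lowered by enzalutamide (12.6 if independent) and for 62 genes lowered by DHT and raised by enzalutamide (10.1). The same direction was called for 10 raised genes (10.5) and 25 lowered genes (12.2). The 2 comparisons share the vehicle arrays, which by itself gave a correlation of 0.501 in simulations, and the measured r was -0.10.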

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

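The kept probes with no single gene name, which no comparison used, also changed. Of 5296 such probes, 480 (9.06%) changed with DHT against vehicle, 34 (0.642%) with enzalutamide against vehicle, 34 (0.642%) with dexamethasone added to enzalutamide, 2 (0.0378%) in the combination against vehicle and 70 (1.32%) in the difference between dexamethasone and DHT. The shares among named genes were 21.7%, 1.83%, 3.50%, 1.10% and 6.90%. No explanation was tested.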

How the results depend on the processing

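No called gene that the naming rule chose for a comparison of groups changed sign in the settings where such genes were followed. These were median scaling, no background correction, the authors' values, both blocks and each array left out. They were not followed with the mean of a gene's probes, where 2467 of 2476 DHT calls kept their sign. Of the 35 list medians that passed, 4 changed sign under median scaling. All 4 stayed below the median of all genes there, so that the common shift gave these signs. The number was 0 with the authors' values, without background correction, with the technical sets or without vehicle replicate 3. Alternatives within 1.5 times the reported values, or on the same side of the threshold, numbered 127 for the answers to the comparisons, and 69 differed; for named genes 1967 calls were kept and 268 lost, and for lists 223 and 22. The stricter filter gave 354 genes for enzalutamide against vehicle, 208 for the combination against vehicle and 183 for the genes called back by dexamethasone. Without background correction these were 410, 253 and 205, with 614 for dexamethasone, 1210 for the difference and 373 shared calls. Normexp with an offset of 50 gave 191 for the combination against vehicle. Median scaling gave 1169 (DHT), 48 (enzalutamide), 108 (dexamethasone), 175 (difference), 60 shared calls, 27 called back and a share of 80.8%, with fry no longer past its threshold. Trend and robust spread gave 427, 616, 263 and 1207 for enzalutamide, dexamethasone, the combination and the difference. The groups alone gave 36, 223 and 10 for the first 3 of these, with fewer arrays to estimate the spread, and a minimum of 1.5-fold gave 890 for DHT and 104, 160 and 60. Within the first technical set, chosen after the data were seen, DHT, enzalutamide, dexamethasone, the combination and the difference gave 995, 0, 0, 0 and 1 genes, and within the second 329, 0, 31, 0 and 10; these hold 6 arrays each. The estimated correlation left 4 lists for the combination against vehicle, and fry passed 15 with DHT. Apart from the sets and the groups alone, the cause was not tested.

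Leaving out 1 array gave 1874 to 2116 genes for DHT, 76 to 133 for enzalutamide, 219 to 245 for dexamethasone, 32 to 66 for the combination and 547 to 706 for the difference, 148 to 245 shared calls, 69.0% to 72.1% for the share, and 47 to 86 called back; 195 calls of named genes were lost and 1020 kept.

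The numbers of the labels do not state that arrays pair, so the replicate number as a block is an alternative only. It gave 2582, 193 and 362 genes for the first 3 of these comparisons and 796 for the difference. With it CXCL8 lost its call in both combination comparisons, HMGCS1 and ENO2 with dexamethasone, MMP7, PTGER4 and DDIT3 in the combination against vehicle, and NR3C2, MSMO1 and UGT2B15 with enzalutamide. The technical block cost PTGER4, DDIT3 and CXCL8 their call against vehicle. Both blocks cost the glucocorticoid-induced list its call with enzalutamide, the luminal list with dexamethasone and the sterol list against vehicle, and the replicate block also the androgen synthesis list with DHT. In residuals 9 of 12 arrays correlated best with arrays of their own number, and 11 of 18 pairs of the same number correlated above 0.1. Signal over background limits NR3C1 and PER1, detected on 0 arrays, and the genes given as bounds.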

Other observations

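Tests of the shared enzalutamide arrays, of enzalutamide arrays low by chance, of ER stress genes within technical sets and of a weaker androgen-like signal were chosen after the results were seen, as were the division of the cell cycle list and the technical sets of arrays.

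Among the 60 genes that enzalutamide lowered and dexamethasone raised, DHT raised 31, lowered 13 and left 16 uncalled. Of the 13 lowered by both DHT and enzalutamide and raised with dexamethasone, 9 are replication and checkpoint genes or related regulators. This grouping was made after the values were seen and was not tested for enrichment. The others are GRIN3A, HSD17B6, TMEFF2 and SDC1. The 9 are GINS2 (-0.87, -0.88 and 0.78), CDC45 (-0.68, -0.78 and 0.72), UHRF1 (-0.96, -0.73 and 0.64), MCM10 (-1.06, -0.64 and 0.53), CHEK1 (-0.74, -0.60 and 0.52), CDC25A (-0.98, -0.85 and 0.50), MCM4 (-1.35, -0.69 and 0.49), FEN1 (-0.63, -0.54 and 0.47) and E2F2 (-0.76, -0.57 and 0.44). In the combination against vehicle the 9 had negative values, from -0.06 (CDC45) to -0.35 (CDC25A). Their rise with dexamethasone was thus a return toward the vehicle level and not past it. Under median scaling 5 of these 9 passed with DHT, 0 with enzalutamide and 2 with dexamethasone, with no change of sign. The genes MCM10, CHEK1, FEN1, E2F2 and CDC25A lost a call with enzalutamide or dexamethasone without at least 1 array. Of 11 replication genes of the cell cycle list, 9 fell with DHT (median -0.63), 3 with enzalutamide (median -0.38) and 1 rose with dexamethasone (median 0.20), while 3 of 18 mitosis genes rose with DHT (median 0.23; 0 of the cell cycle list rose without vehicle replicate 3 and 1 under median scaling) and 0 passed with enzalutamide (0.01) or dexamethasone (0.06).

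Lists of 4 basal, 4 stromal and 4 immune genes were too small for a list test. With DHT CD44 (0.67 ± 0.15, with probes of opposite sign) and ACTA2 (0.65 ± 0.10) rose and CD14 fell (-0.87 ± 0.09). LUM, a stromal list member, was the 1 gene of the 12 that passed with enzalutamide, and with dexamethasone LUM fell (-0.88 ± 0.17) and ACTA2 rose (0.61 ± 0.10). In the combination against vehicle 0 of them passed in limma, with 0.43 ± 0.10 for ACTA2, 0.36 ± 0.17 for LUM and -0.28 ± 0.15 for CD44. MS4A1 was at least 1.10-fold lower and CD79A at least 1.09-fold higher there, without passing. DST and NGFR, detected on 3 arrays each, did not pass. NR3C2, the steroid receptor gene tested, had values of -0.17 ± 0.12 with DHT (with probes of opposite sign) and 0.14 ± 0.12 in the combination against vehicle.

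The return of enzalutamide-changed genes with dexamethasone could come from enzalutamide arrays that deviated by chance, since both comparisons share them. Of the 115 genes called back, 62.6% were called with DHT in the direction opposite to enzalutamide, where DHT called 1259 up and 1217 down of all 11414 genes. Among all genes called with enzalutamide, DHT raised 50.9% of the 114 lowered and lowered 65.3% of the 95 raised. The share argues against chance deviation of the enzalutamide arrays as the whole source of the enzalutamide changes, although DHT and enzalutamide share the vehicle arrays. It is close to that of all enzalutamide calls, so it cannot decide whether the return itself came from the shared arrays. With the technical sets as a block 123 genes were called back. Enzalutamide and combination hold equal numbers of arrays of each set, so the block could not alter the size of the dexamethasone changes. It could alter the enzalutamide changes, and for these the count argues against an additive shift between the sets as the whole cause. A glucocorticoid response at part of the same genes stays a hypothesis, since dexamethasone alone was not among the groups.

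Replication genes fell with DHT while mitosis genes did not. Under median scaling, in which arrays keep their own distributions, the replication median still lay -0.854 from the mitosis median, which argues against the normalization as the whole cause. DHT and vehicle hold equal numbers of arrays of each technical set, so an additive shift between the sets cancels. The smaller of the differences within the sets was -0.798, with 2 arrays per group in the first set and 1 in the second. No biological explanation was tested.

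ER stress genes rose with dexamethasone, which low enzalutamide arrays might mimic. Against vehicle, which uses no enzalutamide-only array, the median was 0.490, which argues against low enzalutamide arrays as the whole cause. Enzalutamide and combination hold equal numbers of arrays of each technical set, so an additive shift between the sets cancels, and the smaller of the medians within the sets was 0.703. Their median with DHT, on other arrays, was 0.56. No biological explanation was tested.

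A hypothesis was that dexamethasone acted as a weaker androgen-like signal and in no other way. Of the 400 genes called with dexamethasone, 80 differed from the DHT change and were opposite to it (66, of which 26 were called with DHT) or larger (14). A return toward vehicle could give part of these, since enzalutamide had called 33 in the other direction. Against vehicle 25 of the 80 passed in the direction of dexamethasone, and 21 of these were detected on all arrays. Without any 1 array 5 of the 21 kept all these calls: SCNN1A (1.49 with dexamethasone, 0.05 with DHT and 1.38 against vehicle), IL1R1 (1.14, 0.33 and 0.83), HPGD (-0.95, 1.94 and -0.73), HSPA5 (0.93, 0.18 and 0.75) and BCL6 (0.69, 0.19 and 0.62). Under median scaling SCNN1A alone of the 5 kept them. These 5 argue against a weaker androgen-like signal as the whole of the response, if such a signal moves each gene in the direction of DHT and no further, which 1 dose of DHT cannot show. The test is the third form tried, each limit being set after values were seen. The first used all 80 (20% of the 400) and was left because of the return toward vehicle. The second used the 25 (6.25%) against limits of 5% and 10%, which the hypothesis does not give. A partly androgen-like signal beside another stays open.

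For DHT, enzalutamide, dexamethasone and the combination against vehicle, 1 of 10 splits of the 6 arrays, the real one, gave as many genes (2476, 209, 400 and 125; highest other 0, 0, 1 and 0), and the same held for the genes called back (115, highest other 1). With 10 splits the share cannot fall below 0.1. For the shared calls, 1 of 100 drawn splits gave as many, the real one (240, highest other 26). Of the 99 others 98 shared 0 calls, because mixed groups gave few calls to share, so this count does not decide whether chance can be excluded. For the difference, 6 of 100 splits gave as many genes (788, highest other 2079), and chance cannot be excluded by that count. All 6 kept DHT and vehicle apart, the highest with these mixed was 11, and the split with 2079 swapped the dexamethasone and enzalutamide arrays. Splits that mixed dexamethasone and enzalutamide arrays and kept DHT and vehicle apart gave 483 to 1042 genes. The DHT change alone can thus give a count as large as 788.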
